A study of Mus musculus with 4 samples.

How the data were processed

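Single-cell RNA was measured in 4 droplet libraries of sorted mouse intestinal epithelium, 2 from the distal colon (DC) and 2 from the 8th section of the small intestine (Si8). Per the labels, the mice were of the RedMUC298trTg strain, which carries an mCherry reporter of goblet cells, and were 6 to 8 weeks old. Cells were released with EDTA and DTT and then with collagenase and DNase, and sorted by mCherry signal. Whether a library holds mCherry-positive cells alone, and how many mice stand behind each, is not given in the sources used here. The deposited values are counts, namely raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 2.1.1 on the mm10 build. No normalization had been applied to them. The gene annotation version is not stated, so coordinates were taken by Ensembl identifier from GENCODE M21 (GRCm38), where 28418 of the 28694 identifiers (99.0%) were found.

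Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, 10522 of 10827. Doublets were scored with Scrublet in scanpy 1.11.5, one library at a time. Its own threshold marked 0.139% of all barcodes, so the highest scores were removed instead, up to an expected rate of 0.8% per 1000 cells. That took out 296 cells and left 10226. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes within libraries, without any gene of the fixed lists, were standardized in each library and reduced to 30 principal components. Each cell was joined to its 5 nearest neighbours by cosine distance in each library, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) was run at a resolution of 1.0. Clusters of fewer than 200 cells were clustered again.

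A cluster took the name of a cell class when its 50 top genes held at least 3 markers of that class, more than of any other, and the first 10 did not favour another class. Top genes were ranked by fold over the other cells with 10 CPM added, at 50 CPM or more, averaged over libraries with at least 10 cells of the cluster, or over all its cells pooled where no library had 10. Clusters of low depth whose first 10 genes held no marker of their class were left unnamed. The names carry "-like" because they rest on RNA alone. This gave 17 clusters, of which 4 were goblet-like (clusters 1, 4, 5 and 6) and 1 (cluster 7) had no name.

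UMIs were summed over the cells of a class within a library, and the library was the unit of replication. Tissues were compared with the edgeR 4.0.16 quasi-likelihood test (TMM scaling, filterByExpr with a minimum count of 10, Benjamini-Hochberg threshold of 0.05). Log2 fold changes are DC minus Si8. The contrast of the 2 goblet-like clusters with the largest mean share of goblet-like cells, 5 minus 1, used sums per cluster and library with library as a block. Each library held at least 20 cells in both clusters. Its results were counted for genes of the fixed lists alone, since those genes took no part in clustering. The interaction of this contrast with tissue was tested on the same sums. It was counted over all tested genes, also those that took part in clustering. Levels are CPM, UMIs scaled to the library's own total, given as mean ± SD, while fold changes carry the TMM factors. For goblet-like cells those factors were 1.20 and 1.17 in DC and 0.855 and 0.830 in Si8, so folds are shifted against ratios of CPM. The median log2 fold change over all tested genes was 0.0435 with TMM and 0.538 with library totals alone. For all cells it was 0.0373 and 0.447. In the cluster contrast it was -0.00495 and -0.287, and in the interaction 0.0146 and 0.296.

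The 28 gene lists, 889 genes in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Camera sets a list against all other tested genes, so its direction is relative to them. With an estimated correlation it rests on the few residual degrees of freedom of these libraries, so a list can hardly pass there. They cover goblet, small intestinal absorptive, colonic absorptive, Paneth, enteroendocrine, tuft, stem, cycling, immune and stromal markers. Function lists cover mucus components, transmembrane mucins, secretory transcription factors, O-glycosylation, ER folding, ion transport, antimicrobial defence, MHC class II, interferon response, regional patterning, surface epithelium, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, xenobiotic metabolism, dissociation stress, mitochondrially encoded and sex-linked genes. Stromal markers had too few tested genes for camera, which left 27 lists. For 8 symbols the tables had no entry. Dmbt1, Gsdmc4, Muc17, Hes1 and Mxd1 are recalled as genes the study reported from these samples and give no independent evidence. Class shares were compared with an exact two-sided permutation test, which with 2 against 2 libraries cannot go below p = 0.333, single shares carry exact Clopper-Pearson 95% intervals, and a count of 0 has an upper limit of 3 counts of the total.

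Named genes followed a rule. For each tissue comparison these were the 6 genes with the largest change in each direction past the threshold, with at least 50 CPM in the higher tissue and no overlap between tissues. From each list came up to 2 passing members per direction, or the 2 most abundant where none passed. Goblet identity genes (Muc2, Fcgbp, Clca1, Zg16, Tff3, Agr2, Spdef, Atoh1) were always named. The cluster contrast used the list rule, and the interaction took the 5 largest in each direction. Where a tissue had 0 UMIs, the fold is a bound against a floor of 3 counts over the tissue. With 1 to 3 UMIs the ratio has a 95% counting interval. Some genes picked by the rule are not reported here, and no others took their place.

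Lists, comparisons, tests, the naming rule and most alternatives were set before the data were examined. Alternatives covered DESeq2 1.42.0, RLE size factors, no count filter, a replicate block, each library left out, looser (200 genes) and stricter (1000 genes, 10% mitochondrial) cell filters, doublets kept, list genes kept in clustering, a resolution of 0.5, tissues clustered separately, cycling-like clusters left out (none was goblet-like), cells thinned to 2000 UMIs and an equal makeup of clusters. Chosen after seeing the data were library totals alone as scaling, single goblet-like clusters, cluster 6 left out, cluster 7 or cycling-like cells added, subtraction of free RNA, the 10 most abundant genes left out, and the tests of absorptive-like, cycling-like and stem-like cells. Tested on simulated data, the edgeR test recovered 70.1% of genes changed by a log2 fold of 1 in goblet-like sums with 14 false calls, and 13.5% in sums over all cells. Camera recovered 20 of 20 shifted lists and called 1 of 500 unshifted ones. The versions were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Empty droplets were not used here, so free RNA was estimated from Paneth genes in absorptive-like cells of Si8, and the DC libraries, where this could not be done, were given the mean of the Si8 estimates, 2.08%.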

Results

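Gene expression was measured in single mouse cells, with 2 libraries from the distal colon and 2 from the 8th section of the small intestine. The libraries DC 1, DC 2, Si8 1 and Si8 2 held 1937, 5098, 1536 and 2256 cell barcodes. Their total UMI counts were 27136824, 66880457, 26075303 and 53675821. Median UMIs per barcode were 13393, 12162.5, 17700 and 21127, and median genes per barcode 3249, 3113.5, 3083 and 3653. Mitochondrial transcripts took a median of 5.35% and 5.23% of the UMIs of a barcode in DC and 2.90% and 3.70% in Si8. After filtering, 1829, 4711, 1490 and 2196 cells remained. The goblet-like cells among them numbered 999, 2236, 758 and 1014. Sums over goblet-like cells correlated across genes at r = 0.987 between both DC libraries and 0.988 between both Si8 libraries, genes not being independent replicates. All 4 libraries held the Y-linked gene Ddx3y, at 72.0 and 58.6 CPM in DC and 35.9 and 27.5 CPM in Si8, while Xist had 1, 4, 1 and 0 UMIs. Nothing in the labels says that the libraries come from separate animals. The p-values thus measure only the spread between these samples, or between genes for camera at the preset correlation. Intervals and floors cover counting error alone.

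The first question was which genes set the sorted cells of the distal colon apart from those of the small intestine, whatever their class. Across all kept cells, the colon was marked by the posterior homeobox gene Hoxb13 and the small intestine by alpha-defensins, the antimicrobial peptides of Paneth cells. Hoxb13 (ENSMUSG00000049604, chromosome 11, 96194316 to 96197447) averaged 441 ± 19.7 CPM in DC (mean ± SD, n = 2 libraries per tissue here and throughout the tissue comparisons) and had no UMI in Si8, which makes it at least 11429.5-fold higher in DC. Defa21 (chromosome 8, 21025545 to 21026516) had no UMI in DC and 4566 ± 2837 CPM in Si8, at least 135454-fold lower in DC.

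Other genes with no UMI in Si8 were Nov, which encodes a matricellular signalling protein, the carbonic anhydrase Car1, the transglutaminase Tgm3, Nxpe2 and the proton pump subunit Atp12a. Nov (chromosome 15, 54745702 to 54754039) averaged 138 ± 71.3 CPM in DC and was at least 3579.6-fold higher. Car1 (chromosome 3, 14766216 to 14808368) averaged 93.2 ± 26.8 CPM, at least 2415-fold higher. Tgm3 (chromosome 2, 130012349 to 130050399) stood at 76.9 ± 48.2 CPM, at least 1995-fold higher. Nxpe2 (chromosome 9, 48318006 to 48353454) stood at 55.5 ± 15.2 CPM, at least 1439.6-fold higher, and Atp12a (chromosome 14, 56365068 to 56388550) at 53.7 ± 30.6 CPM, at least 1393-fold higher. On the small intestinal side, Gm14850 averaged 1041 ± 444 CPM and Gm21002 864 ± 358, both with no UMI in DC. They were at least 30893-fold and 25623-fold lower in DC. Defa20 (chromosome 8, 21509258 to 21510237) had 1 UMI in DC against 531113 in Si8, a ratio of 607695 with a 95% counting interval of 109069 to 24002700.0. Gm15308 also had 1 UMI in DC, and its ratio was 383040.0 with an interval of 68748 to 15129300.0. Defensin genes are close in sequence, so which of them each UMI came from is uncertain. The edgeR adjusted p of these genes ranged from 0.000179 to 0.00209, and in each both libraries of one tissue lay above both of the other.

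In total 3267 of 13105 tested genes passed the threshold across all cells, 1699 higher and 1568 lower in DC. The count was 5160 with library totals alone, of which 80.6% were higher in DC in place of 52.0%, and 2698 genes were shared. The count fell to 1603 without DC 1 and to 1565 without DC 2.

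The main comparison asked how goblet cells themselves differ between the regions. In goblet-like cells 11 of 15 listed mucus genes were lower in DC and 4 higher (camera adjusted p = 0.00758, and adjusted p = 0.463 with an estimated correlation). The gel-forming mucin Muc2 was 3.04-fold lower in DC and Tff3, a trefoil peptide secreted with it, 7.8-fold lower. Colonic goblet-like cells had Hoxb13 and the anion channel gene Best2, with no UMI of either in Si8, while UMIs of the antibacterial lectin genes Reg3b and Reg3g and of several defensins were more frequent in Si8. Absorptive-like cells of Si8 held Reg3b at 35675 and 18819 CPM and Reg3g at 20389 and 10833, above the goblet-like cells of the same libraries, and free RNA was estimated at 1.21% and 2.96% of UMIs there.

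Of the goblet identity genes, Tff3 (chromosome 17, 31125306 to 31129646) averaged 15102 ± 2719 CPM in DC and 83432 ± 822 in Si8, a log2 fold change of -2.96 ± 0.19 (SE; adjusted p = 3.05e-05). Zg16 (chromosome 7, 127050156 to 127087328), a lectin that binds bacterial cell walls, averaged 14866 ± 1759 and 75902 ± 11695 CPM, a log2 fold change of -2.85 ± 0.20. The mucus protein genes Clca1 (chromosome 3, 145003817 to 145032776) and Fcgbp (chromosome 7, 28071236 to 28120862) fell by 2.60 ± 0.19 and 2.39 ± 0.15 on the log2 scale in DC against Si8. Clca1 averaged 1553 ± 389.9 CPM in DC and 6644 ± 253 in Si8, and Fcgbp 2655 ± 233 and 9871 ± 1023. Muc2 (chromosome 7, 141690340 to 141754693) averaged 5097 ± 1014 CPM in DC and 11011 ± 333 in Si8, a log2 fold change of -1.60 ± 0.18 (adjusted p = 0.000393). Agr2 (chromosome 12, 35992907 to 36004087), a disulfide isomerase needed for mucin folding, averaged 15386 ± 2848 and 33086 ± 717 CPM, also at -1.60 ± 0.18. Spdef (chromosome 17, 27714352 to 27728955), a transcription factor of goblet cell maturation, averaged 157 ± 14.2 CPM in DC and 213 ± 3.55 in Si8, a log2 fold change of -0.94 ± 0.11. Atoh1 (chromosome 6, 64729125 to 64731245), which commits progenitors to the secretory lineage, averaged 396 ± 161 CPM in DC and 203 ± 8.45 in Si8 and did not pass in the planned test (log2 fold change 0.46, adjusted p = 0.156). It passed with replicate number as a block, without the count filter (adjusted p = 0.00395), with library totals alone (0.00961) and in cluster 6 alone (0.0279). Its adjusted p across alternatives ran from 0.000500 without DC 2, where the log2 fold change was 0.82, to 0.985 without DC 1, where it was -0.0039.

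**Figure D1:**
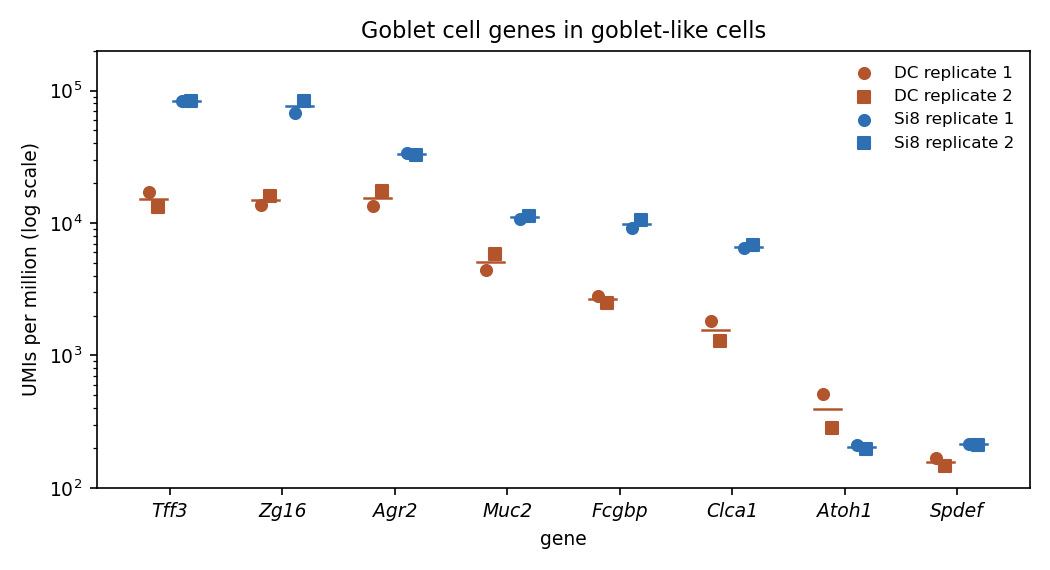
Goblet identity genes in goblet-like cells, with CPM on a log axis, one point per library and a line at the mean of each tissue (n = 2 libraries). Zg16 averages 14866 CPM in DC and 75902 in Si8, and Atoh1 is the one gene with the higher mean in DC, at 396 against 203 CPM.

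Among the largest changes in goblet-like cells, 6 genes had no UMI in Si8. Hoxb13 averaged 424 ± 29.2 CPM in DC, at least 4750.4-fold higher, and Best2 (chromosome 8, 85007202 to 85014531) 318 ± 54.5 CPM, at least 3558-fold higher. Nov averaged 221 ± 139 CPM and was at least 2481-fold higher. Thbs4 (chromosome 13, 92751590 to 92794818), an extracellular matrix protein gene, averaged 63.2 ± 14 CPM, the chymase gene Cma1 (chromosome 14, 55941451 to 55944675) 57.4 ± 8.66, and the protease inhibitor gene Slpi (chromosome 2, 164354070 to 164389095) 56.7 ± 4.42. They were at least 708-fold, 643-fold and 636-fold higher in DC. In the other direction, Reg3b (chromosome 6, 78370657 to 78373466) had 2 UMIs in DC and 128498 in Si8, where it averaged 3961 ± 1238 CPM. The ratio was 70047, with a 95% counting interval of 19391 to 578405. Reg3g (chromosome 6, 78466269 to 78468872) averaged 0.164 ± 0.119 CPM in DC and 6988 ± 2774 in Si8. Defa24 (chromosome 8, 21734494 to 21735471) had 3 UMIs in DC and 6489.5 ± 811 CPM in Si8, a ratio of 78162 with an interval of 26745 to 379019. Defa17 (chromosome 8, 21655780 to 21656735) at 412 ± 102 CPM, Defa20 at 313 ± 176 and Gm15308 at 186 ± 135 in Si8 had no UMI in DC, and were at least 5027-fold, 3819-fold and 2278-fold lower there. These 12 genes had adjusted p values between 1.28e-06 and 0.000231.

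In all, 5277 of 11699 genes differed between goblet-like cells of DC and Si8, 2591 higher and 2686 lower in DC. The scaling by library totals alone put 83.1% of 7720 genes higher in DC in place of 49.1%, with 3894 shared. Goblet-like cells of Si8 were deeper, at median UMIs of 19501 and 19173.5 per cell against 12555 and 10672 in DC. With every cell thinned to 2000 UMIs the count was 2619, of which 2520 were shared. It was 3493 with cycling-like cells included, 2671 in cluster 1 alone, 3035 in cluster 4 and 2417 in cluster 6. Cluster 6, whose top genes include Mptx1 and the stress genes Cyr61, Atf3 and Ddit3, made up 29.5% and 23.6% of goblet-like cells in DC and 8.71% and 8.19% in Si8. Cluster 5 took 18.8% and 15.8% in DC and 23.1% and 46.4% in Si8.

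Gene lists were then asked which functions and cell type programs moved together between goblet-like cells of the regions. With the preset correlation 12 of 27 lists passed, 11 lower and 1 higher in DC, and with an estimated correlation 0 passed. The smallest unadjusted camera p with an estimated correlation was 0.0433, for surface genes. With 4 libraries that test has little power, so a miss there does not show a list to be unchanged. The strongest were protein folding in the endoplasmic reticulum, the interferon response, goblet markers and small intestinal absorptive markers, all lower in DC. All genes named in this comparison except Atoh1 and Pdgfrb passed, the highest adjusted p among the others being 0.0438 for Isg20. Both libraries of one tissue lay above both of the other in CPM for all of them but Top2a, Cycs and Ndufa9.

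Protein folding genes were lower in DC almost throughout. In the list of ER folding and unfolded protein response 38 of 46 genes were lower and 1 was higher in DC, against 39 and 2 adjusted over the list alone (camera adjusted p = 2.35e-11). The adjusted p = 0.553 with an estimated correlation. The median log2 fold change of the list was -0.97, and -0.48 with library totals alone, where 30 were lower and 5 higher. Trib3, a stress-induced pseudokinase, averaged 0.225 ± 0.0917 CPM in DC and 6.44 ± 5.18 in Si8. Chac1, a glutathione-degrading enzyme of the stress response, averaged 3.54 ± 0.318 and 47.5 ± 50.7 CPM. The exception was Ern1, a sensor of unfolded protein, at 18.6 ± 2.83 CPM in DC and 7.13 ± 1.80 in Si8.

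Goblet markers and mucus components were mostly lower in DC. Goblet markers were lower for 38 and higher for 11 of 55 genes, as adjusted over the list alone (camera adjusted p = 5.18e-06). The adjusted p = 0.463 with an estimated correlation, and 31 of the 58 listed genes also belong to another list. Library totals alone put 29 lower and 14 higher. The chemokine gene Ccl9 averaged 11.2 ± 6.89 CPM in DC and 274 ± 12.2 in Si8, and Tmed6, of vesicle trafficking, 0.734 ± 0.133 and 8.48 ± 2.90. Best2 led the other direction with Nxpe2, which stood at 3.38 ± 3.42 CPM in DC and had no UMI in Si8 (at least 37.9-fold higher). Of 15 mucus genes 11 were lower and 4 higher, as adjusted over the list alone (camera adjusted p = 0.00758), with adjusted p = 0.463 with an estimated correlation. That list holds Dmbt1, reported from these samples. Itln1, an intelectin that binds microbial sugars, averaged 7.85 ± 2.26 CPM in DC and 728 ± 40.8 in Si8. The salivary-type protein gene Sval1 averaged 8823 ± 1131 CPM in DC and 237 ± 8.02 in Si8, and Tgm3 7.54 ± 7.38 CPM in DC with no UMI in Si8 (at least 84.4-fold higher). The mucus call was lost in cluster 5 alone (adjusted p = 0.0776) and with the 10 most abundant genes left out (0.550), within a range from 8.73e-07 to 0.550 over its alternatives.

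Most listed genes of the glycocalyx and of surface epithelium also stood lower in DC, though the membrane mucins Muc4 and Muc1 stood higher. Transmembrane mucins and glycocalyx genes were lower for 9 and higher for 2 of 14, as adjusted over the list alone (camera adjusted p = 0.00218). The adjusted p = 0.463 with an estimated correlation. The galectin gene Lgals2 averaged 12.3 ± 2.81 CPM in DC and 11129 ± 185 in Si8. Podxl, a sialomucin gene, had no UMI in DC and 3.07 ± 1.95 CPM in Si8 (at least 37.5-fold lower). Muc4 averaged 72.8 ± 16.2 CPM in DC and 21.5 ± 6.23 in Si8, and Muc1 had 361 UMIs in DC against 3 in Si8, a ratio of 110.4 with a 95% counting interval of 37.5 to 538. In the list of surface and late differentiation epithelium 28 of 48 genes were lower and 7 higher, 29 and 8 adjusted over the list alone (camera adjusted p = 0.000567). The adjusted p = 0.463 with an estimated correlation, and the list holds the genes recalled from this study. Library totals alone gave 21 lower and 14 higher. The keratin gene Krt20 averaged 19.2 ± 1.35 CPM in DC and 671 ± 78 in Si8, and the transglutaminase gene Tgm2 0.284 ± 0.0507 and 13.7 ± 1.51. Annexin A1 (Anxa1) was higher in DC, at 49.2 ± 5.87 against 0.112 ± 0.0590 CPM, as was Slfn4, at 36.5 ± 0.877 against 3.42 ± 1.56.

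Interferon response genes were the second group that fell as a block in DC. There 33 of 40 were lower and 2 higher, as adjusted over the list alone (camera adjusted p = 2.59e-10). The adjusted p = 0.553 with an estimated correlation. Oas3, a sensor of double-stranded RNA, averaged 0.104 ± 0.146 CPM in DC and 6.81 ± 2.36 in Si8, and Usp18, which restrains interferon signalling, 0.142 ± 0.0254 and 4.10 ± 1.5. The antiviral gene Rsad2 was higher in DC, at 42.3 ± 5.69 against 11.8 ± 1.11 CPM, and so was Isg20, at 34.2 ± 0.471 against 18.2 ± 3.89. Antigen presentation genes of MHC class II were lower for 6 and higher for 1 of 7, as adjusted over the list alone (camera adjusted p = 0.00655), with adjusted p = 0.553 with an estimated correlation. The call was lost with fry (adjusted p = 0.0591), within a range from 3.63e-06 to 0.0591. Cd74, the invariant chain, averaged 1.41 ± 0.408 CPM in DC and 161 ± 86.3 in Si8, and H2-Aa 0.683 ± 0.966 and 32.1 ± 13.7. Ctss, a protease that cleaves the invariant chain, was higher in DC, at 47.9 ± 1.84 against 6.40 ± 0.0422 CPM.

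Immune cell markers moved the same way as the MHC class II and interferon genes. Of 7 tested, 5 were lower and 0 higher in DC, 6 and 0 adjusted over the list alone (camera adjusted p = 0.00218), with adjusted p = 0.463 with an estimated correlation. The list shares Cd74 and Lyz2 with others. The granzyme gene Gzma had no UMI in DC and 1.21 ± 0.613 CPM in Si8 (at least 14.8-fold lower). In cluster 5 alone the call was lost (adjusted p = 0.0943), within a range from 3.21e-06 to 0.0943.

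Antimicrobial genes split by region. Of 35, 19 were lower and 10 higher in DC, 21 and 11 adjusted over the list alone (camera adjusted p = 0.0435), with adjusted p = 0.73 with an estimated correlation. Reg3b and Reg3g led the small intestinal side. Slpi and Wfdc2, both encoding WAP domain proteins, led the colonic side, Wfdc2 at 198 ± 22.7 CPM in DC and 1.53 ± 0.132 in Si8. The call was lost in cluster 5 alone (adjusted p = 0.265), with the 10 most abundant genes left out (0.0941), with tissues clustered separately (0.0583) and with fry (0.0591), within a range from 3.72e-06 to 0.265. Paneth markers were lower for 20 and higher for 3 of 24, 20 and 4 adjusted over the list alone (camera adjusted p = 1.36e-05), with adjusted p = 0.463 with an estimated correlation. Defa24 and Defa17 led them. Mptx1, a pentraxin gene, and the colipase gene Clps went the other way, Mptx1 at 35061 ± 6709.6 CPM in DC and 20.4 ± 2.59 in Si8 and Clps at 565 ± 207 and 21.4 ± 5.73. Paneth-like cells made up 1.01% and 1.96% of kept cells in Si8, where absorptive-like cells held Paneth transcripts at levels that correspond to 1.21% and 2.96% of free RNA.

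**Figure D2:**
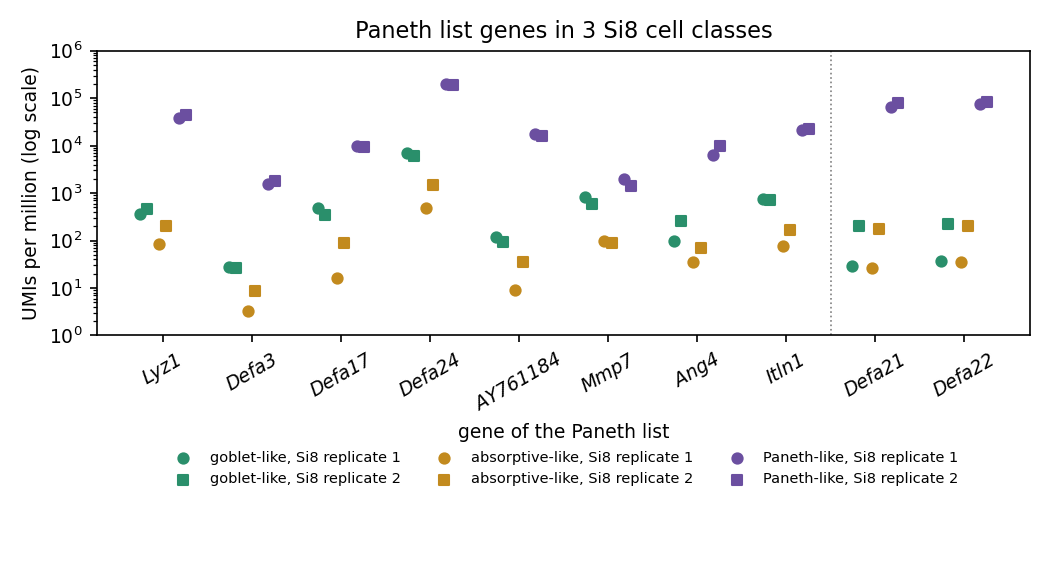
Paneth list genes in goblet-like, absorptive-like and Paneth-like cells of Si8, with CPM on a log axis and one point per library. Left of the dotted line stand 8 genes whose goblet-like points lie above the absorptive-like points, and right of it Defa21 and Defa22, where both lie at one level.

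**Figure D3:**
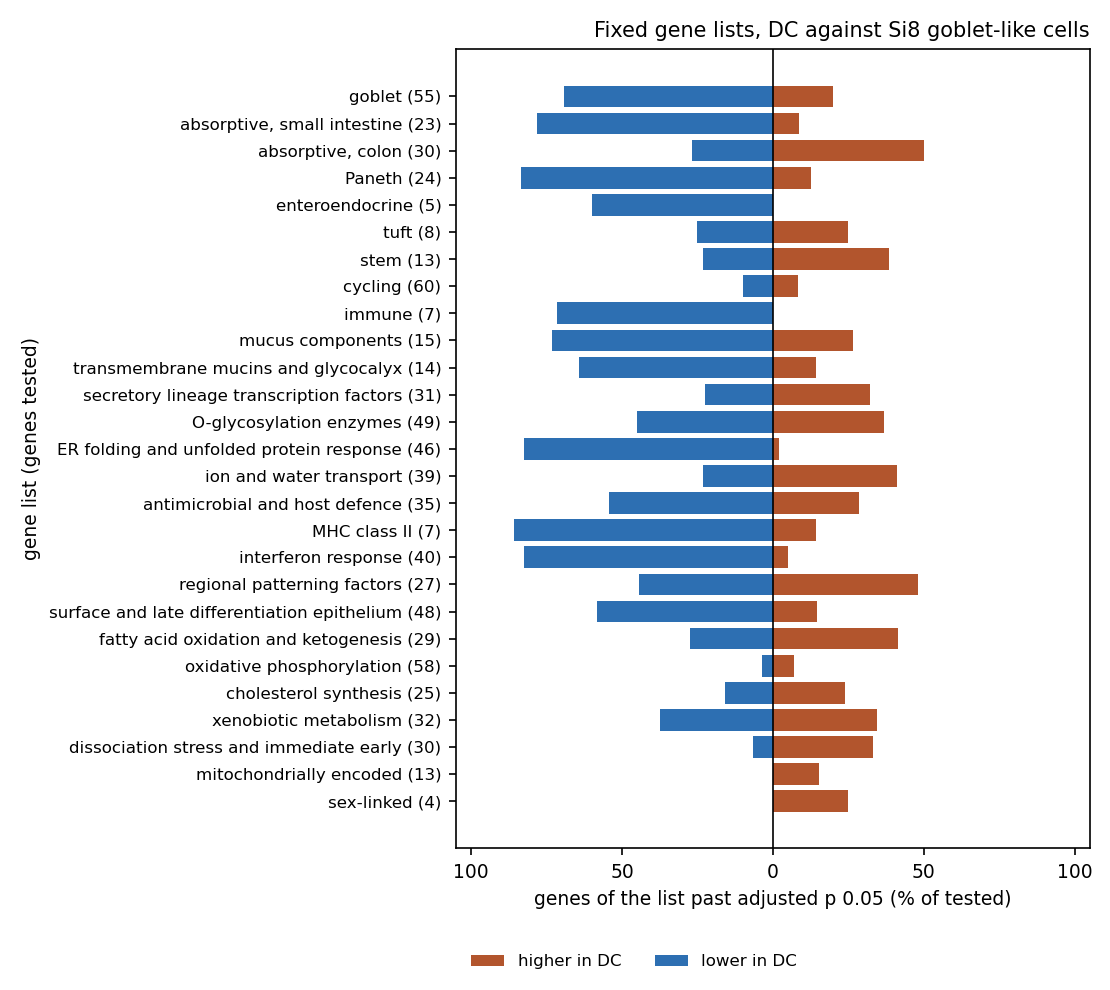
Fixed gene lists in goblet-like cells, with bars for the percent of the tested genes (number in brackets) that passed as higher (right) or lower (left) in DC than in Si8. Of 40 interferon response genes 33 are lower and 2 higher, and of 46 ER folding genes 38 are lower and 1 higher, against 28 and 2 and 30 and 5 with library totals alone.

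Small intestinal absorptive markers were mostly lower in DC, for 18 of 23 genes with 2 higher, as adjusted over the list alone (camera adjusted p = 5.18e-06), with adjusted p = 0.553 with an estimated correlation. Free RNA was estimated at 1.21% and 2.96% of UMIs in Si8, where absorptive-like cells held Sis at 249 and 373 CPM and Apoa1 at 1007 and 310.2. Apoa1, an apolipoprotein gene, stood at 11.6 ± 1.75 CPM in Si8 and the disaccharidase gene Sis at 3.54 ± 1.61, with no UMI in DC (at least 141-fold and 43.2-fold lower). The aminopeptidase gene Anpep was higher in DC, at 13.9 ± 5.85 against 1.92 ± 0.118 CPM, as was the fructose kinase gene Khk, at 20.7 ± 1.22 against 10.2 ± 1.58. Colonic absorptive markers were higher for 15 and lower for 8 of 30, 16 and 8 adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.401). Car1 at 12.9 ± 5.23 CPM and the sodium channel gene Scnn1b at 7.83 ± 1.94 CPM in DC had no UMI in Si8 (at least 145-fold and 87.7-fold higher). The bile acid transporter gene Slc51a had no UMI in DC and 6.19 ± 3.16 CPM in Si8 (at least 75.6-fold lower).

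Patterning factors showed opposite sets in each region. Of 27, 13 were higher and 12 lower in DC, 13 and 13 adjusted over the list alone (camera adjusted p = 0.823), and the median and mean of the list differed in sign. Hoxa7 joined Hoxb13 at 29.2 ± 7.61 CPM in DC and no UMI in Si8 (at least 327-fold higher). The transcription factor genes Osr2 at 51 ± 10.6 CPM and Gata5 at 27.4 ± 4.94 CPM in Si8 had no UMI in DC (at least 623-fold and 335-fold lower). Secretory transcription factors were higher for 10 and lower for 7 of 31, 10 and 8 adjusted over the list alone (camera adjusted p = 0.823), and 16 and 4 with library totals alone. Mean and median of that list also had opposite signs, and it holds Hes1 and Mxd1, reported from these samples. The forkhead gene Foxa2 averaged 98.2 ± 19.5 CPM in DC and 19.6 ± 2.05 in Si8, and Myc 25.7 ± 10.3 and 5.18 ± 0.231. The homeobox gene Isx was lower, at 0.676 ± 0.390 against 59.3 ± 7.73 CPM, and Mxd1, an antagonist of Myc, at 35.5 ± 2.44 against 72.4 ± 10.

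Enzymes of O-glycosylation, which build mucin glycans, were exchanged more than shifted. There 18 were higher and 22 lower of 49, as adjusted over the list alone (camera adjusted p = 0.544). Its mean and median had opposite signs, and with library totals alone 22 were higher and 17 lower and camera passed (adjusted p = 0.0387, in a range from 0.0387 to 0.953). The median of the list was then 0.365, below the 0.538 over all tested genes, against which camera sets a list. Gcnt1, a branching enzyme of core 2 glycans, averaged 63.7 ± 6.87 CPM in DC and 0.854 ± 0.191 in Si8. The sulfotransferase gene Chst5 stood at 1.81 ± 0.158 CPM in DC with no UMI in Si8 (at least 20.3-fold higher). B4galnt1 averaged 1.70 ± 0.818 CPM in DC and 161 ± 16.2 in Si8, and Gcnt2 had 2 UMIs in DC against 270 in Si8, a ratio of 147 with a 95% counting interval of 40.4 to 1222. Ion and water transport genes were higher for 16 and lower for 9 of 39, 17 and 12 adjusted over the list alone (camera adjusted p = 0.607), and 23 and 9 with library totals alone. It passed in cluster 5 alone (adjusted p = 0.0449, in a range from 0.0449 to 0.956). Atp12a at 56.2 ± 28.4 CPM in DC had no UMI in Si8 (at least 629-fold higher). The carbonic anhydrase-related gene Car8 averaged 3.68 ± 0.689 CPM in DC and 131 ± 2.01 in Si8, and Clca4b had 1 UMI in DC against 45 in Si8, a ratio of 49.1 with an interval of 8.37 to 1980.3.

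Metabolic lists did not pass in the planned test, though some did in alternatives. Fatty acid oxidation and ketogenesis had 12 higher and 8 lower of 29, 14 and 9 adjusted over the list alone (camera adjusted p = 0.544), with median and mean of opposite sign, and 17 and 4 with library totals alone. It passed as higher in DC with fry (adjusted p = 0.0387, in a range from 0.0387 to 0.87). The lipid droplet gene Plin2 averaged 50.6 ± 2.76 CPM in DC and 8.78 ± 0.0700 in Si8. Cyp4f14 averaged 0.166 ± 0.234 and 7.27 ± 0.689 CPM, and Angptl4, an inhibitor of lipoprotein lipase, 0.163 ± 0.00392 and 0.861 ± 0.0180. Cholesterol synthesis had 6 higher and 4 lower of 25, as adjusted over the list alone (camera adjusted p = 0.909), again with median and mean of opposite sign. Insig1 averaged 118 ± 20.6 CPM in DC and 50.9 ± 2.39 in Si8, Hsd17b7 22.9 ± 2.33 and 9.48 ± 0.321, and Ebp 122 ± 8.97 and 199.7 ± 13.4. Cholesterol genes were higher for 18 and lower for 3 with library totals alone.

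Xenobiotic enzymes had 11 higher and 12 lower of 32, as adjusted over the list alone (camera adjusted p = 0.677). With library totals alone 18 were higher and 12 lower, and camera passed as lower relative to the other genes (adjusted p = 0.03, in a range from 0.03 to 0.865). The median log2 fold change of the list was then 0.437, against 0.538 over all tested genes. The cytochrome gene Cyp2d34 averaged 38.9 ± 4.76 CPM in DC and 0.218 ± 0.0909 in Si8, and the sulfotransferase gene Sult1a1 17 ± 8.06 and 0.103 ± 0.145. Cyp2c65 at 6.05 ± 1.14 CPM in Si8 had no UMI in DC (at least 73.9-fold lower), and the carboxylesterase gene Ces1f averaged 0.911 ± 1.29 and 24.8 ± 2.53 CPM. Oxidative phosphorylation had 4 higher and 2 lower of 58, 0 and 0 adjusted over the list alone (camera adjusted p = 0.68). With library totals alone 51 were higher and 0 lower, and the list passed as higher in DC (adjusted p = 0.000694, in a range from 0.000694 to 0.776). It also passed in cluster 4 alone (0.0322). Ndufa5 averaged 281 ± 16.6 CPM in DC and 139 ± 5.97 in Si8, Ndufs1 45.7 ± 0.281 and 23.5 ± 1.59, and cytochrome c (Cycs) 405 ± 5.89 and 437 ± 73.6. Ndufa9 had a log2 fold change of -0.39 with TMM and 0.10 with library totals alone, at 102 ± 13.4 CPM in DC and 95.2 ± 0.848 in Si8. Mitochondrially encoded genes had 2 higher and 0 lower of 13, 0 and 0 adjusted over the list alone (camera adjusted p = 0.119, in a range from 0.00107 to 0.809), where mt-Co2 averaged 6476 ± 271 CPM in DC and 3417 ± 257 in Si8 and mt-Nd6 10.1 ± 0.103 and 4.44 ± 0.985. Library totals alone put 12 of these 13 higher in DC, and the list then passed (0.0300). It also passed without DC 2 (0.0227), with the looser cell filter (0.0249), doublets kept (0.0468), a resolution of 0.5 (0.0491), cells thinned to 2000 UMIs (0.00961) and in cluster 5 alone (0.00107).

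Genes of dissociation stress formed the only list that passed as higher in DC. There 10 were higher and 2 lower of 30, as adjusted over the list alone (camera adjusted p = 0.0314), with adjusted p = 0.553 with an estimated correlation. The small heat shock gene Hspb1 averaged 18.9 ± 1.30 CPM in DC and 0.209 ± 0.00459 in Si8, and the early response gene Nr4a1 638 ± 197 and 64 ± 6.77. Socs3, at 3.47 ± 0.636 and 16.6 ± 13.3 CPM, and Gadd45b, at 51.4 ± 3.40 and 82.2 ± 25.6, were lower. The call was lost with library totals alone (21 higher and 2 lower, adjusted p = 0.100), with cycling-like cells included (0.0518), without cluster 6 (0.0908) and in cluster 1 alone (0.139), within a range from 0.000396 to 0.139. The list was higher in DC in classes tested after seeing the data as well, for 15 genes with 3 lower in absorptive-like cells, 15 with 1 lower in cycling-like cells and 7 with 0 lower in stem-like cells (camera adjusted p = 0.0039, 0.00088 and 0.00215, and adjusted p = 0.728, 0.801 and 0.563 with an estimated correlation). Cluster 6, which carries stress genes, held the larger share in DC, and mitochondrial transcripts took a median of 5.35% and 5.18% of a goblet-like cell's UMIs in DC against 2.90% and 2.85% in Si8.

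The remaining marker lists did not pass in the planned test. Stem cell markers had 5 higher and 3 lower of 13, 8 and 3 adjusted over the list alone (camera adjusted p = 0.272), and 10 and 2 with library totals alone. Ascl2, a transcription factor of stem cells, averaged 3.10 ± 0.305 CPM in DC and 0.312 ± 0.141 in Si8, and the cotransporter gene Slc12a2 422 ± 146 and 122 ± 19.5. Prom1, at 26.4 ± 1.47 and 75.6 ± 8.47 CPM, and Smoc2, at 7.01 ± 0.493 and 11 ± 0.534, were lower. Cell cycle genes had 5 higher and 6 lower of 60, 4 and 4 adjusted over the list alone (camera adjusted p = 0.892), against 19 higher and 1 lower with library totals alone, and passed as higher without Si8 2 (adjusted p = 0.0214, in a range from 0.0214 to 0.956). The mitotic kinase gene Aurkb averaged 6.43 ± 0.421 CPM in DC and 1.13 ± 0.504 in Si8, Rrm1 7.28 ± 1.47 and 2.09 ± 0.963, H2afx 24.5 ± 1.19 and 59.6 ± 4.31, and Top2a 7.30 ± 3.31 and 11 ± 2.31. Tuft markers had 2 higher and 2 lower of 8, as adjusted over the list alone (camera adjusted p = 0.823), and 4 and 2 with library totals alone, Lrmp at 90.9 ± 14.2 CPM in DC and 4.42 ± 2.25 in Si8, Gng13 at 2.60 ± 0.628 and 0.633 ± 0.195, Kctd12 at 1.53 ± 0.469 and 5.73 ± 0.396 and Avil at 0.366 ± 0.0488 and 1.12 ± 0.0861. Enteroendocrine markers had 3 lower and 0 higher of 5, as adjusted over the list alone (camera adjusted p = 0.124, in a range from 0.00378 in cluster 6 alone to 0.566 without DC 1), and passed without Si8 1 (0.0335) and without DC 2 (0.0198). The tachykinin gene Tac1 averaged 2.38 ± 1.55 CPM in DC and 166 ± 156 in Si8, and the prohormone convertase gene Pcsk1 0.921 ± 0.396 and 5.59 ± 0.492. Of 2 stromal markers tested with edgeR 0 passed, with or without adjustment, and the pericyte marker Pdgfrb averaged 0.858 ± 0.308 CPM in DC and 0.565 ± 0.000119 in Si8 (adjusted p = 0.785). Among 4 sex-linked genes 1 passed, as adjusted over the list alone (camera adjusted p = 0.607), and 3 with library totals alone, Ddx3y at 75.5 ± 11.5 CPM in DC and 31.1 ± 5.39 in Si8.

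The makeup of the sorted cells was compared next. Goblet-like cells were the largest class in every library, at 54.6% (exact 95% interval 52.3 to 56.9) and 47.5% (46.0 to 48.9) of kept cells in DC and 50.9% (48.3 to 53.4) and 46.2% (44.1 to 48.3) in Si8. Cycling-like cells made up 21.5% and 22.6% in DC and 11% and 24.5% in Si8, absorptive-like cells 11.6% and 20.6% against 7.25% and 13.7%, and stem-like cells 5.85% and 6.62% against 3.62% and 7.65%. Paneth-like cells numbered 15 and 43 in Si8. The 1 and 10 DC cells that fell in the same clusters held no UMI of Lyz1, Mmp7, Defa17 or Defa24 and few UMIs (medians per cluster from 4080.5 to 6372, against 32396 to 103532 in Si8), so they are not taken as Paneth-like. The unnamed cluster 7 took 6.40% and 2.17% in DC and 25.6% and 5.69% in Si8.

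The mean goblet-like share was 51% ± 5.06 in DC and 48.5% ± 3.32 in Si8, a difference of 2.52 points (exact permutation p = 0.667). Differences were 4.25 points for cycling-like cells (exact p = 1), 5.61 for absorptive-like (exact p = 0.667), 0.599 for stem-like (exact p = 1) and -11.4 for cluster 7 (exact p = 0.667). Enteroendocrine-like cells numbered 0, 7, 4 and 4 (exact p = 0.333) and immune-like cells 0, 11, 2 and 0 (exact p = 1). Tuft-like cells numbered 0, 0, 4 and 2 (exact p = 0.333). A count of 0, taken as 3 counts of the total, allows a share of up to 0.164% in DC 1, 0.0637% in DC 2 and 0.137% in Si8 2. No class share could reach the threshold with 2 libraries per tissue, and the goblet-like difference turned to between -8.79 and -10.2 points under 4 other cell settings. In each of those a cluster with the leading genes of cluster 7, among them Saa1, Ido1, Slfn4 and Mxd1, was named goblet-like. Counting cluster 7 as goblet-like, chosen after seeing the data, gave -8.83 points in the clusters used here, so the sign of this difference depends on that name. Zg16 stood at 78576 and 88378 CPM in cluster 7 of DC and at 143649 and 206048 in Si8. Goblet-like cells held it at 13622 and 16110 CPM in DC and 67632 and 84171 in Si8. The planned comparison of goblet-like cells thus leaves out cells high in this mucus gene.

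**Figure D4:**
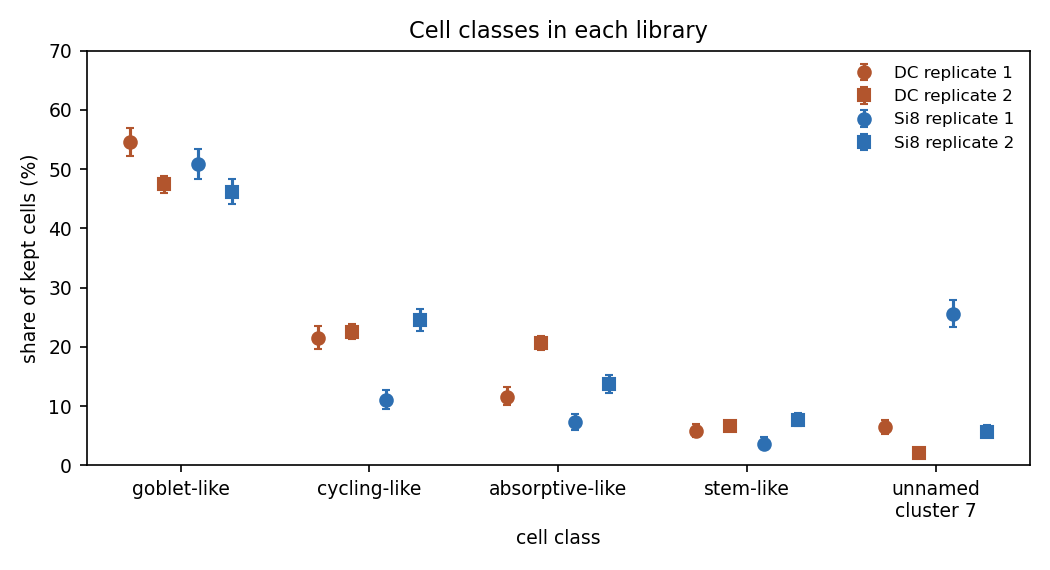
Share of kept cells per class in percent, one point per library with its exact 95% interval. Goblet-like cells lie between 46.2% and 54.6% in the 4 libraries, and cluster 7 is at 25.6% in Si8 1.

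Within goblet-like cells, the contrast of the 2 clusters with the largest mean share over libraries asked how goblet cells vary inside each tissue. In both DC libraries cluster 5 was the smallest of the 4 goblet-like clusters. Cluster 5 had the higher levels of surface and interferon genes, and cluster 1 those of proliferation and stem cell genes, though with an estimated correlation none of these lists passed (adjusted p = 0.207, 0.484, 0.188 and 0.188). From cluster 1 to cluster 5, Zg16 rose from 10968 ± 13061 to 93392 ± 36160.1 CPM (mean ± SD over all 4 libraries) and Clca1 from 1447 ± 1509 to 8022 ± 2708. The galectin gene Lgals3 rose from 185 ± 97.8 to 1551 ± 399 CPM, whereas Reg4, a secreted lectin gene, fell from 4082 ± 4124 to 559 ± 608. Each of these 4 genes moved in that direction in 4 of 4 libraries, and so by CPM did the other named genes that passed, at adjusted p between 9.8e-05 and 0.048. Exceptions were Ang4, Bex2, Cd74, Gal3st1, Trib3, Ifit1, Cdx2, mt-Co1, Kdm5d and Uty with 3 of 4 libraries, and Nupr1, Itln1, Cyp4f14, mt-Nd4, Scnn1g, Scnn1b, Nxpe2, Habp2 and Defa17 with 2 of 4. Of these, Scnn1g, Scnn1b and Nxpe2 had no UMI in either cluster of Si8, and Habp2 and Defa17 none in either of DC.

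Of 645 list genes tested 335 passed, 198 higher and 137 lower in cluster 5, and 256 of them also passed with library totals alone, where 35.2% of 338 were higher in place of 59.1%. Clusters 1 and 5 held 277, 657, 345 and 241 cells and 188, 354, 175 and 470 cells in DC 1, DC 2, Si8 1 and Si8 2. Standard deviations span both tissues, whose levels differ, while the test compares clusters within each library.

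Surface genes rose in cluster 5. Of 46 surface and late differentiation genes 30 were higher and 3 lower, 32 and 3 adjusted over the list alone (camera adjusted p = 2.15e-09), with adjusted p = 0.207 with an estimated correlation. The list holds the genes recalled from this study. Espn, an actin bundler of microvilli, rose from 5.98 ± 1.38 to 47 ± 29.2 CPM, while Cd177 fell from 94 ± 20 to 15.2 ± 13.3 and Guca2b, a guanylin peptide gene, from 446 ± 89.4 to 66.5 ± 32.1. The list of transmembrane mucins and glycocalyx had 9 higher and 0 lower of 13 (camera adjusted p = 9.17e-06). Adjusted over the list alone 10 were higher and 0 lower, and camera gave adjusted p = 0.188 with an estimated correlation. Ceacam20, an adhesion molecule of the apical membrane, rose from 0.929 ± 0.626 to 4.24 ± 1.70 CPM. Colonic absorptive markers were higher for 18 and lower for 0 of 28, 23 and 0 adjusted over the list alone (camera adjusted p = 3.18e-08), with adjusted p = 0.188 with an estimated correlation, and 9 and 0 with library totals alone. The sodium channel genes Scnn1g and Scnn1b rose from 0.126 ± 0.145 to 7.86 ± 10.1 CPM and from 0.659 ± 0.762 to 14.8 ± 17.6, with the rise in the 2 DC libraries alone. Small intestinal absorptive markers were higher for 8 and lower for 1 of 18, as adjusted over the list alone (camera adjusted p = 0.00546), with adjusted p = 0.484 with an estimated correlation, and 5 and 2 with library totals alone. Rbp2, a retinol carrier, rose from 4.15 ± 2.47 to 17.7 ± 12.1 CPM and Gsta1 from 4.05 ± 3.41 to 16.7 ± 19.7.

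The interferon response also rose in cluster 5, where 29 of 37 were higher and 2 lower, 30 and 2 adjusted over the list alone (camera adjusted p = 1.53e-10), with adjusted p = 0.484 with an estimated correlation. Ifit1 rose from 1.06 ± 1.40 to 7.57 ± 8.88 CPM and Ifit1bl1 from 1.40 ± 1.43 to 9.97 ± 12.6, while Isg20 fell from 33.6 ± 5.49 to 14.8 ± 6.70 and Irf8 from 45.2 ± 11.1 to 23.9 ± 11.4. MHC class II genes moved the other way, with 5 of 7 lower and 0 higher, as adjusted over the list alone (camera adjusted p = 0.0101) and adjusted p = 0.511 with an estimated correlation. Cd74 fell from 160.3 ± 187 to 24.3 ± 30.0 CPM and H2-Eb1 from 23.9 ± 26.6 to 3.86 ± 4.05. Cholesterol synthesis genes were higher for 17 and lower for 0 of 25, 18 and 0 adjusted over the list alone (camera adjusted p = 5.63e-06), with adjusted p = 0.499 with an estimated correlation, and 8 and 2 with library totals alone. The squalene synthase gene Fdft1 rose from 77.2 ± 12.1 to 142 ± 36.1 CPM. Xenobiotic enzymes were higher for 12 and lower for 4 of 29, 12 and 5 adjusted over the list alone (camera adjusted p = 0.0394), with adjusted p = 0.499 with an estimated correlation, and 9 and 6 with library totals alone. Cyp2d34 rose from 6.01 ± 7.38 to 60.2 ± 69.7 CPM and Sult1b1 from 3.70 ± 3.06 to 17.1 ± 8.06, and Gsta3 fell from 6.56 ± 3.74 to 1.56 ± 1.01 and Gstm1 from 102 ± 49.3 to 47 ± 20.1.

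Proliferation and stem cell genes were lower in cluster 5. Of 52 cell cycle genes 38 were lower and 0 higher, 39 and 0 adjusted over the list alone (camera adjusted p = 1.53e-10), with adjusted p = 0.188 with an estimated correlation. The mitotic cyclin gene Ccnb2 fell from 11 ± 6.47 to 1.63 ± 1.16 CPM and the histone gene Hist1h1b from 2.20 ± 1.05 to 0.422 ± 0.304. Stem cell markers were lower for 8 and higher for 0 of 13, 9 and 0 adjusted over the list alone (camera adjusted p = 0.000519), with adjusted p = 0.188 with an estimated correlation. Smoc2 fell from 19.6 ± 7.39 to 2.25 ± 0.942 CPM and Clca3b from 35.7 ± 19.3 to 3.38 ± 3.60. Oxidative phosphorylation genes were lower for 19 and higher for 1 of 58, 20 and 1 adjusted over the list alone (camera adjusted p = 3.49e-05), with adjusted p = 0.499 with an estimated correlation, and 50 were lower with library totals alone. Ndufa4 fell from 1126 ± 86.7 to 640.0 ± 45.8 CPM and Ndufa10 from 159 ± 27.5 to 89.6 ± 25.8, while Ndufa6 rose from 498 ± 118 to 576 ± 75.2. Paneth markers were lower for 11 and higher for 2 of 24, as adjusted over the list alone (camera adjusted p = 0.0495), with adjusted p = 0.703 with an estimated correlation, and 12 and 0 with library totals alone. Habp2 fell from 3.45 ± 4.02 to 0.0804 ± 0.161 CPM and Defa17 from 384 ± 451 to 31.7 ± 45.7, and Ang4 rose from 82.5 ± 91.4 to 184 ± 106 and Nupr1 from 681 ± 265 to 1022 ± 691.

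**Figure D5:**
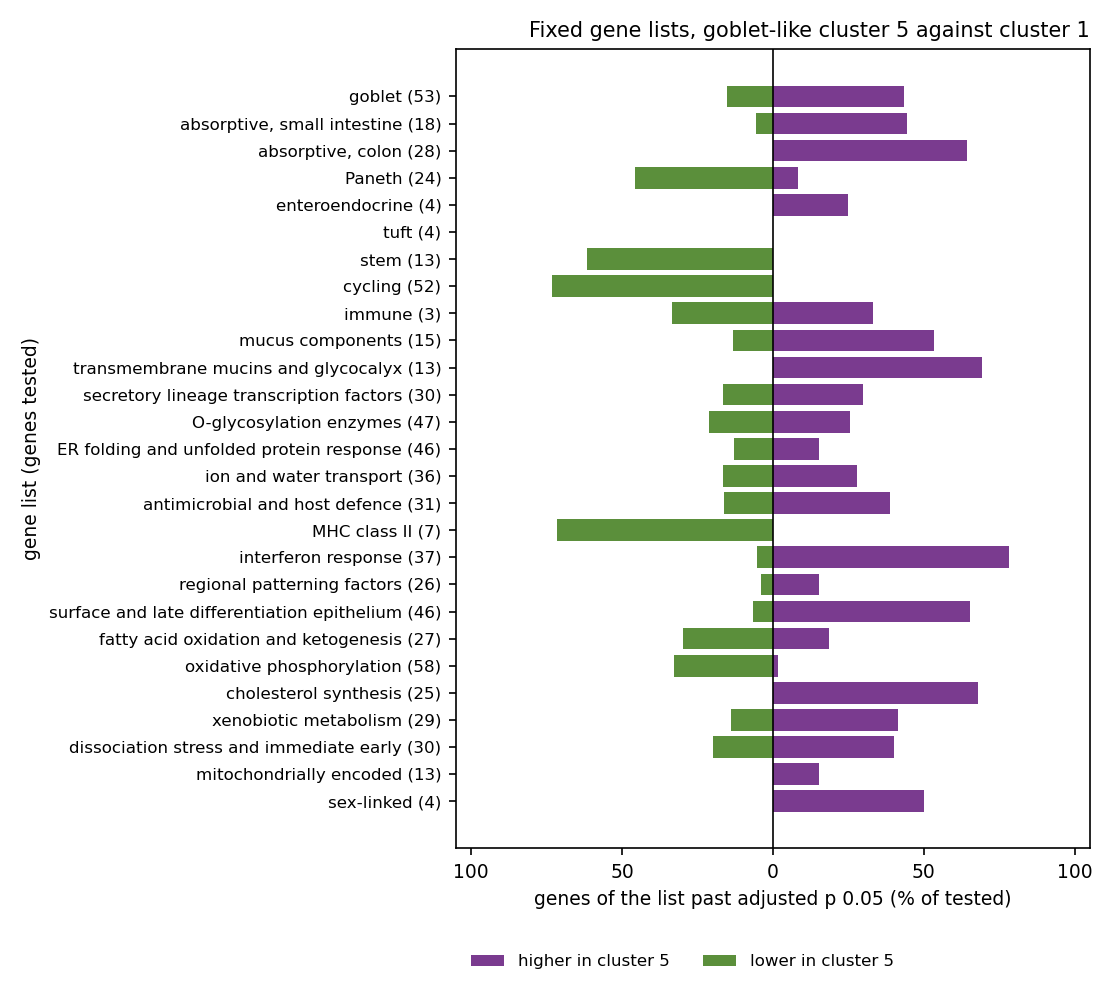
Fixed gene lists between goblet-like clusters 5 and 1 across 4 libraries, with bars for the percent of the tested genes (number in brackets) that passed as higher (right) or lower (left) in cluster 5. Of 37 interferon response genes 29 are higher and 2 lower, and of 52 cycling genes 0 are higher and 38 lower.

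Goblet markers were higher for 23 and lower for 8 of 53 in cluster 5, 25 and 8 adjusted over the list alone (camera adjusted p = 0.0195), with adjusted p = 0.499 with an estimated correlation. Library totals alone put 16 higher and 16 lower. Tmed6 fell from 8.17 ± 8.00 to 1.66 ± 1.92 CPM and Nxpe2 from 2.61 ± 4.27 to 0.801 ± 1.31. Mucus components had 8 higher and 2 lower of 15, 9 and 2 adjusted over the list alone, and missed the threshold as a list (camera adjusted p = 0.0516), with 7 higher and 4 lower with library totals alone. Itln1 fell from 581 ± 667 to 129 ± 151 CPM. Secretory transcription factors had 9 higher and 5 lower of 30, 10 and 5 adjusted over the list alone (camera adjusted p = 0.367), and 5 higher and 9 lower with library totals alone. Klf4 rose from 335 ± 75.8 to 1079 ± 473 CPM and Mxd1, recalled from this study, from 21.2 ± 6.13 to 119 ± 47.6. Sox9, a factor of progenitors, fell from 109 ± 36.9 to 40.1 ± 39.8 CPM, and the Notch ligand gene Dll1 from 63 ± 17.5 to 19.8 ± 6.30. O-glycosylation enzymes had 12 higher and 10 lower of 47, 13 and 10 adjusted over the list alone (camera adjusted p = 0.793), with median and mean of opposite sign, and 3 higher and 16 lower with library totals alone. The branching enzyme gene Gcnt3 rose from 178 ± 113 to 313 ± 63 CPM and Gal3st1 from 7.81 ± 0.393 to 13.7 ± 6.71. Fut1, a fucosyltransferase gene, fell from 3.14 ± 1.33 to 0.0268 ± 0.0536 CPM and A4gnt, whose enzyme caps glycans with N-acetylglucosamine, from 11.9 ± 2.70 to 0.651 ± 0.703.

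ER folding genes had 7 higher and 6 lower of 46 in cluster 5, as adjusted over the list alone (camera adjusted p = 0.884), and 2 higher and 16 lower with library totals alone. The stress factors Ddit3 and Trib3 rose from 114 ± 28.8 to 224 ± 71.8 CPM and from 2.17 ± 2.71 to 4.96 ± 7.72. Pdia5 fell from 287 ± 44.2 to 99.4 ± 12.9 CPM and Fkbp11 from 354 ± 182 to 150.2 ± 65.6. Ion transport genes had 10 higher and 6 lower of 36, 11 and 6 adjusted over the list alone (camera adjusted p = 0.584), with median and mean of opposite sign, and 7 higher and 11 lower with library totals alone. The water channel gene Aqp1 fell from 11.2 ± 7.77 to 1.25 ± 1.25 CPM. Antimicrobial genes had 12 higher and 5 lower of 31, 13 and 5 adjusted over the list alone (camera adjusted p = 0.114), and 8 and 8 with library totals alone, with Sprr2a2 from 0.189 ± 0.243 to 3.94 ± 3.17 CPM and lysozyme (Lyz1) from 323 ± 343 to 112 ± 154. Stress genes had 12 higher and 6 lower of 30, 14 and 6 adjusted over the list alone (camera adjusted p = 0.356), and 3 and 7 with library totals alone. Ier5 rose from 20.8 ± 4.73 to 38 ± 11.5 CPM and Cyr61 from 255 ± 71.9 to 424 ± 133, and the metallothionein gene Mt2 fell from 96.9 ± 82.7 to 16 ± 10.6 and Hsph1 from 33.8 ± 16.5 to 12.7 ± 7.07.

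Fatty acid oxidation genes had 5 higher and 8 lower of 27, as adjusted over the list alone (camera adjusted p = 0.273), with median and mean of opposite sign, and 3 and 15 with library totals alone. Slc25a20, the carnitine carrier, rose from 12.4 ± 3.12 to 31.5 ± 11.7 CPM and Cyp4f14 from 1.80 ± 1.78 to 6.10 ± 6.89, and Slc27a2 fell from 9.36 ± 6.56 to 3.65 ± 2.33 and Bdh1 from 61.3 ± 13.5 to 32.2 ± 11.4. Patterning factors had 4 higher and 1 lower of 26, 1 and 1 adjusted over the list alone (camera adjusted p = 0.699), and 0 and 2 with library totals alone. The caudal homeobox gene Cdx2 rose from 45.4 ± 36.5 to 54.6 ± 48.4 CPM. Mitochondrially encoded genes had 2 higher and 0 lower of 13, 1 and 0 adjusted over the list alone (camera adjusted p = 0.0151), with adjusted p = 0.66 with an estimated correlation. With library totals alone 0 passed. Between the clusters mt-Co1 stood at 8491 ± 1752 and 11257 ± 4845 CPM and mt-Nd4 at 2215 ± 251 and 2290.1 ± 702. Immune markers had 1 higher and 1 lower of 3, as adjusted over the list alone (camera adjusted p = 0.771), AW112010 rising from 364 ± 387 to 1315 ± 1151 CPM. Enteroendocrine markers had 1 higher of 4, as adjusted over the list alone (camera adjusted p = 0.546), and 0 with library totals alone, Bex2 at 25.2 ± 14.9 and 29.7 ± 7.87 CPM. Of 4 tuft markers 0 passed (camera adjusted p = 0.85), edgeR giving Lrmp at 41.7 ± 46.1 and 44.3 ± 46.3 CPM and Kctd12 at 3.99 ± 3.08 and 3.63 ± 2.52. Of 4 sex-linked genes 2 were higher, as adjusted over the list alone (camera adjusted p = 0.169), and 0 with library totals alone, Kdm5d at 12.1 ± 1.54 and 15.4 ± 3.46 CPM and Uty at 14.5 ± 5.58 and 16.4 ± 6.50. No stromal marker could be tested.

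Whether this contrast differs between the regions was tested as an interaction. The rise of the mucus genes Zg16 and Clca1 from cluster 1 to cluster 5 was steeper in DC, where Zg16 went from 719 ± 465 to 62865 ± 11727 CPM and Clca1 from 213 ± 10.2 to 5699 ± 457. In Si8 Zg16 went from 21216 ± 9561 to 123920.0 ± 7576 CPM and Clca1 from 2681 ± 858 to 10346 ± 453. Plpp1, a lipid phosphatase gene, fell from 245 ± 13.8 to 49.4 ± 2.88 CPM in DC and rose from 6.87 ± 1.32 to 19 ± 1.76 in Si8. Interaction log2 fold changes were 3.70 for Zg16 (adjusted p = 0.0005), 2.48 for Clca1 (adjusted p = 0.00015) and -4.07 for Plpp1 (adjusted p = 7.7e-06).

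Further genes with the lower change in DC were the detoxifying genes Ces1f and Gsta4, Bglap3 and Rsad2. Gsta4 stood at 6.83 ± 1.02 and 5.44 ± 0.428 CPM in clusters 1 and 5 of DC and at 12.4 ± 0.289 and 99.1 ± 36.7 in Si8. Ces1f stood at 1.73 ± 2.45 and 0.274 ± 0.387 CPM in DC and 8.10 ± 4.10 and 41 ± 0.534 in Si8, Bglap3 at 3.69 ± 1.97 and 6.91 ± 1.84 against 0.470 ± 0.358 and 15.4 ± 17, and Rsad2 at 34.5 ± 12 and 32 ± 5.00 against 2.39 ± 1.54 and 21.6 ± 0.371. The genes with the largest opposite change had no UMI in cluster 5 of Si8, so their fitted values are no bounds. Serpina9 stood at 24 ± 3.57 and 17.8 ± 2.66 CPM in DC and 5.96 ± 2.91 and 0 in Si8, and Lypd6b at 12.6 ± 1.27 and 14.7 ± 5.56 against 4.01 ± 1.08 and 0. Rgs16 stood at 15.8 ± 7.85 and 40.7 ± 16.5 CPM in DC and 1.12 ± 0.561 and 0 in Si8, Apobec2 at 12 ± 2.54 and 13.1 ± 3.36 against 1.95 ± 2.14 and 0, and Frmd6 at 1.44 ± 0.238 and 3.51 ± 0.322 against 0.723 ± 0.203 and 0. In all 672 of 10463 genes passed, 331 with the higher and 341 with the lower change in DC. Unlike the counts of the contrast, these were not limited to list genes. Genes that formed the clusters are thus among those tested, which limits what their p-values mean. The count was 323 without DC 2, 239 with DESeq2, 261 with the looser cell filter and 1116 without the count filter, and with library totals alone 88.4% of 1320 genes had the higher change in DC in place of 49.3%.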

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

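The interaction was planned, and the test over other splits of the cluster sums, as well as library totals as the only scaling, were chosen only after the result was seen. The change from goblet-like cluster 1 to cluster 5 differed between DC and Si8 for 672 genes by the interaction term of edgeR, which is what set these results apart. That count was taken over all tested genes, also those that formed the clusters. Every value below is an interaction log2 fold change, DC minus Si8, for a named gene that passed.

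No gene list was tested for the interaction, so these are values of single genes. Among those with the higher change in DC the value was 3.70 for Zg16 and 2.48 for Clca1. Itln1, which stood at 5.23 and 6.52 CPM in clusters 1 and 5 of DC and 1156 and 251 in Si8, had 2.35. For Reg4 it was 0.88, with a fall in both tissues, from 7641 to 1084 CPM in DC and from 524 to 33.3 in Si8. The glycan branching enzyme gene Gcnt3 had 1.14, and the antimicrobial ribonuclease gene Ang4 2.65. Sox9, a progenitor factor, had 2.17, as it fell from 140.0 to 73.4 CPM in DC and from 78.2 to 6.86 in Si8. Slc25a20, the carnitine carrier, had 1.14, the stress genes Nupr1 and Ddit3 0.89 and 0.79.

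Other genes had the lower change in DC. Espn had -2.27, with levels of 6.58 and 21.7 CPM in DC and 5.39 and 72.3 in Si8. Lgals3 had -1.04 and Mxd1, recalled from this study, -0.74. Cd177 had -1.71 and the metallothionein gene Mt2 -1.23, since both fell further in DC. The interferon factor gene Irf8 had -0.91 and the antiviral gene Rsad2 -3.35. Among metabolic genes the value was -5.16 for Ces1f, -3.57 for Gsta4, -4.07 for Plpp1 and -0.55 for Ndufa6, a subunit of complex I. Bglap3 had -4.38.

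Another 5 genes had no UMI in cluster 5 of Si8, so that their fitted values depend on the prior count and are no bounds. These were 7.85 for Serpina9, 7.67 for Lypd6b, 7.29 for Rgs16, 7.0 for Apobec2 and 6.39 for Frmd6. The count of 672 rested in part on 1 library, at 323 without DC 2.

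For the contrast itself, only the 8 splits of the sums that part both clusters of every library can be compared, since library is a block, and these are too few for a share under 0.05. The real split gave 335 list genes, as 1 of the 8 did, and the highest of the others 0. The clusters were also formed from expression in the same cells.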

How the results depend on the processing

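Library totals as the only scaling, single clusters, cluster 6 left out, cluster 7 included, cycling-like cells included, free RNA subtracted, the 10 most abundant genes left out and the tests of absorptive-like, cycling-like and stem-like cells were chosen only after the result was seen. In goblet-like cells 78 named genes kept direction and side of the threshold under every alternative. All 11 named genes across all cells kept both, and so did 42 of 69 in the cluster contrast, 3 of 10 in the interaction and 7 of 27 lists. Those 7 lists are ones that did not pass in the planned test. No list that passed there kept its side, since none passed with an estimated correlation.

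Counts that moved by more than 1.5 times did so as follows, and except where a smaller number of cells, UMIs or genes shows it, the cause was not tested. All cells gave 5160 with library totals alone, against 3267. Goblet-like cells, at 5277, gave 2619 thinned to 2000 UMIs, 3493 with cycling-like cells, and 2671, 3035 and 2417 in clusters 1, 4 and 6 alone. Lists went from 12 to 0 with an estimated correlation. Stem-like cells went from 1656 to 983 with DESeq2. The interaction, at 672, gave 239 with DESeq2, 1116 without the count filter, 1320 with library totals alone and 261 with at least 200 genes per cell.

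The goblet-like share difference of 2.52 points became -8.79 with at least 200 genes, -10.2 with the stricter filter, -9.59 with doublets kept and -9.18 at resolution 0.5, in which a cluster with the leading genes of cluster 7 was named goblet-like, and -8.83 with cluster 7 counted as goblet-like. The stem-like difference of 0.599 became 7.38 with tissues clustered separately. It has no value with the stricter filter, doublets kept, list genes kept or resolution 0.5, where no cluster was stem-like.

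With 1 library left out, a tissue has a lone library assumed to vary like the other. Counts then ranged from 1565 to 3921 for all cells, 4055 to 4771 for goblet-like, 2544 to 3614 for absorptive-like, 1670 to 3145 for cycling-like and 882 to 2228 for stem-like cells. The cluster contrast ranged from 287 to 290, the interaction from 323 to 802 and lists from 12 to 14. Share differences ranged from -1.06 to 6.10 for goblet-like, 1.11 to 10.1 for absorptive-like, -2.52 to 11 for cycling-like and -1.41 to 2.61 for stem-like cells.

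Reversed log2 fold changes were 0.10 for Ndufa9 with library totals alone. With 1 library left out, Atoh1 ranged from -0.0039 without DC 1 to 0.82. Including cycling-like cells gave 0.11 for Top2a and -0.0267 for Pdgfrb. In the cluster contrast Kctd12 went to -0.11 with library totals alone, -0.52 with at least 200 genes, -0.0601 with the stricter filter, -0.0693 with doublets kept and -0.15 at resolution 0.5. The cause was not tested for any of these.

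Replicate number as a block gave 4269, 6350, 4271, 4281 and 2289 genes for all, goblet-like, absorptive-like, cycling-like and stem-like cells, though no shared animal or day is stated. With it Atoh1 in goblet-like cells passed, at a log2 fold change of 0.41 (adjusted p = 0.0353). Depth limits how many genes can be tested, 8832 in goblet-like cells thinned to 2000 UMIs against 11699. Simulated changes of a log2 fold of 1 were recovered for 70.1% of genes in goblet-like sums and 13.5% in sums over all cells, whose common coefficients of biological variation were 0.119 and 0.191.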

Other observations

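The tests of absorptive-like, cycling-like and stem-like cells and the genes named for those classes were chosen only after the result was seen, and so were the tests of free RNA, doublets, shared reads, abundant genes and cluster 1 alone. Equal makeup of clusters, leaving out Si8 1 and thinning were set before the data were examined, but the bounds they are held to only afterwards. Absorptive-like cells differed by 3646 of 10714 genes between the regions, 1842 higher and 1804 lower in DC. Fabp6, the ileal bile acid binding protein, averaged 19.3 ± 7.0 CPM in DC and 19505 ± 4940.3 in Si8 (n = 2 libraries per tissue), and Fabp2, a fatty acid carrier, 56.9 ± 33.0 and 982 ± 170.0. Colonic cells had the higher levels of Hsd11b2, which inactivates glucocorticoids, at 720.0 ± 93.7 against 75.2 ± 12.8 CPM, and of the membrane mucin Muc3, at 2509 ± 70.6 against 518 ± 40.6. Small intestinal absorptive markers were lower for 22 and higher for 1 of 26 (camera adjusted p = 1.13e-14, and adjusted p = 0.728 with an estimated correlation), and colonic ones higher for 20 and lower for 7 of 31 (camera adjusted p = 0.00895, and adjusted p = 0.728 with an estimated correlation). MHC class II genes were lower for 7 and higher for 1 of 8 in absorptive-like, cycling-like and stem-like cells alike, with Cd74 at 2.00 ± 1.92, 6.48 ± 5.87 and 6.90 ± 0.606 CPM in DC and 865 ± 231, 815 ± 167 and 1146 ± 262 in Si8. Camera gave adjusted p = 0.000122, 1.39e-05 and 7.07e-09, and adjusted p = 0.728, 0.801 and 0.520 with an estimated correlation.

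Cycling-like cells differed by 3047 of 11777 genes (1670 without Si8 2) and stem-like cells by 1656 of 10132 (1065 without DC 1 and 882 without DC 2). Cholesterol synthesis was higher in DC in both, for 11 of 25 genes with 1 lower in cycling-like cells and for 9 with 0 lower in stem-like cells (camera adjusted p = 0.000996 and 9.50e-05, and adjusted p = 0.801 and 0.524 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, averaged 199 ± 8.58 CPM in DC and 115 ± 3.28 in Si8 cycling-like cells, and 156 ± 3.09 and 81.1 ± 4.13 in stem-like cells. In stem-like cells the cell cycle list was lower in DC for 19 and higher for 0 of 60 genes (camera adjusted p = 7.07e-09, and adjusted p = 0.639 with an estimated correlation), with the histone gene H2afz at 650 ± 20.7 and 1118 ± 84.1 CPM. Cluster 7, which got no class name, held Muc2 at 17303 and 13572 CPM in DC and 22048 and 21045 in Si8, above the goblet-like cells of each library. Its cells had median UMIs of 4095 and 4017.5 in DC and 5916 and 13429 in Si8, and mitochondrial transcripts took a median of 10.7% and 11.3% of them in DC and 1.40% and 2.14% in Si8. Mxd1 stood at 1068, 584, 1119 and 527 CPM in DC 1, DC 2, Si8 1 and Si8 2, against 33.8, 37.2, 79.5 and 65.4 in goblet-like cells. Ido1, which degrades tryptophan, stood at 47.7 and 57.9 CPM in DC and 2185 and 738 in Si8, and Saa1, an acute phase protein gene, at 5267 and 3445 in DC and 1038 and 247 in Si8.

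In Si8 goblet-like cells 20 tested Paneth list genes stood higher than in DC. Free RNA from Paneth cells as the source is argued against for 8 of the 20, Lyz1, Defa3, Defa17, Defa24, AY761184, Mmp7, Ang4 and Itln1, whose ratio to absorptive-like cells had a lower 95% limit of 2.21 or more in both Si8 libraries, while for 2, Defa21 and Defa22, one level in both classes is what free RNA would give. Doublets with Paneth cells would keep these genes in 1 ratio to Paneth-like cells, but the highest ratio was 5024 times the lowest in Si8 1 and 887 times in Si8 2, and 1654 and 323 times without Copz2, which stood at 44.5 and 45.5 CPM in goblet-like and 34.6 and 41.3 in Paneth-like cells. Reads shared between defensin paralogs do not concern members outside that family, 4 of 7 of which stood above the other class, so these do not test that explanation. For the defensins, 4 of 13 of which stood above, shared reads cannot be told apart from expression, since the counts do not show which paralog a read matched. The other 10 genes lay between, and 3 of the 26 listed genes belong to other lists. The 8 stood in Si8 goblet-like cells at 0.578% to 42.3% of their level in Paneth-like cells. Expression in Si8 goblet cells themselves may account for these 8 and stays open as a hypothesis.

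Interferon response and MHC class II genes were lower in DC goblet-like cells, 39 of 47 being lower and 3 higher at a median log2 fold change of -1.92, though with an estimated correlation neither list passed (adjusted p = 0.553 each). Immune cells like those of the immune-like cluster are argued against as a source among the goblet-like cells. There 15 abundant genes of that cluster stood at a median of 0.0163 and 0.0234 of the level that the share implied by Cd74 (1.04% and 0.471%) would need. Exceptions were Lcp1 (1.07 and 1.92) and AW112010 (250 and 583). The reference came from 11 cells of DC 2 and 2 of Si8 1, so immune cells of another kind are not covered. A different makeup of clusters is argued against by a median of -1.89 with equal makeup, and Si8 1 standing apart by -1.49 without it. A difference between the epithelium of the regions is a candidate explanation that these tests leave open, as it was not tested.

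ER folding genes were lower in DC goblet-like cells, with a median log2 fold change of -0.97 over 46 genes. They were also lower in absorptive-like, cycling-like and stem-like cells, for 30, 22 and 13 genes with 1, 0 and 0 higher and medians of -0.80, -0.56 and -0.59 (camera adjusted p = 3.08e-07, 2.37e-06 and 7.57e-07, and adjusted p = 0.728, 0.821 and 0.748 with an estimated correlation). The 10 most abundant genes took 15.5% and 14.8% of goblet-like UMIs in DC and 25.8% and 27.0% in Si8, which lowers the share left to all other genes in Si8, so a few abundant genes as the cause are argued against by a median of -0.48 with library totals alone, though part of the size depends on the scaling. Cluster makeup is argued against by a median of -0.90, the value nearer to 0 of cluster 1 alone and equal makeup. With cells thinned to 2000 UMIs the median was -0.91. That value cannot decide on depth per cell, since random thinning leaves the expected share of each gene in a cell unchanged. A difference between the epithelium of the regions may underlie what remains, a hypothesis that was not tested.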
